A study of Danio rerio with 4 samples.

How the data were processed

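The data are 4 RNA-seq libraries of whole zebrafish larvae at 4 days post fertilisation (dpf), 2 of wild-type (WT) fish and 2 of duox mutants, all of the AB strain. Per the labels' protocols, total RNA was made into libraries with an NEB Ultra RNA kit and sequenced on an Illumina HiSeq 2000. Groups and replicate numbers were taken from the titles of the samples, which number the WT libraries 1 and 3 and the mutant libraries 2 and 4. Every per-library column of the expression table was matched to a sample.

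The authors deposited a table of whole-number read counts per gene for 30228 genes, of which 26143 carry Ensembl identifiers and 4085 are new genes that the authors assembled. The same table holds FPKM values by the authors, that is, fragments scaled by transcript length and library total. Per the submitters' processing notes, the tools were HISAT2, Picard, SAMtools 0.1.18 and GATK, with no roles given, and the build is listed as mm9, a mouse build. The gene identifiers are zebrafish ones, and the contig names in the authors' lists of transcript starts, ends and splicing events are those of the zebrafish assembly Zv9, so positions are given as Zv9. The program that counted the reads, its use of strand and its treatment of reads that match several places are not given in the sources used here. Counts of overlapping or antisense genes and of near-identical copies therefore cannot be told apart with certainty. A gene's position is the span of the authors' events for it over the 4 libraries, which 22307 genes have. The authors' deposited list of changed genes gives an FDR (a p-value adjusted for multiple tests) and a log2 fold change of the mutant over WT. A column heading of the authors' table names DESeq with an FDR of 0.01 and a fold change of 2.

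Changed genes were found with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with its quasi-likelihood F test, TMM scaling, the filterByExpr filter by genotype and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was called changed, and 25741 genes passed the filter. Fold changes are log2 of the mutant over WT, with the standard error derived from the F statistic. Levels are counts scaled to the library total after TMM scaling (CPM), as mean ± SD over the 2 libraries of a genotype. The labels do not say whether the 2 libraries of a genotype came from separate clutches or pools, so p-values measure the spread between these libraries, which may be technical. For a gene at 0 counts in both libraries of a genotype, the fold is a lower bound against a floor of 3 counts over that genotype. For a gene with 1 to 3 counts there, the ratio of pooled counts is given with an exact 95% interval. Floors and intervals cover counting error alone.

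Gene lists for 39 pathways and cell types were fixed before the data were examined. Of their 1547 symbols, 1409 (91.1%) were found in the table, directly or through the reference tables of symbols and synonyms. Each list was tested with camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists. Camera was repeated with a correlation estimated per list, and fry was run for each list. Members past the gene test were counted over all genes and adjusted over the list alone.

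Named genes were chosen by a rule written before the data were examined. It takes duox and its maturation factor duoxa. It then takes the 12 largest rises and the 12 largest falls among changed genes that have a gene symbol other than a clone or provisional name, a mean CPM of at least 1 and no overlap between the genotypes. Last, it takes up to 4 members of each list with the smallest adjusted p. Genes named outside the rule are marked as such. Not every gene that the rule takes is named in the text.

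On simulated data made from the means and spread of 25374 real genes for the comparison of mutant with WT, the test recovered 40 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2, none with the wrong sign. The changed genes were drawn from those with a mean CPM of at least 1, so recovery at lower counts was not tested. Of the test's 172 calls, 36 were unchanged genes. Of 39 simulated lists, the 1 that was shifted was called and none of 38 random lists was. The simulated genes varied independently, so false calls of lists whose members vary together were not tested.

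Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, edgeR's exact test, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of mean FPKM of at least 1, no filter on low counts, a mean CPM of at least 1, an added minimum of 1 for the absolute log2 fold change, and leaving out each library. For the lists they were the estimated correlation, fry, RLE scaling, a mean CPM of at least 1, a prior count of 0.5 and leaving out each library. Positions and neighbours were tested in Python 3.11.15 with scipy 1.17.1. Further alternatives were added after the data were seen, namely fits on Ensembl genes alone and fits without genes at 3 or fewer pooled counts in a genotype.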

Results

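Transcript levels were measured by RNA-seq in whole zebrafish larvae at 4 dpf that were WT or mutant for duox, the dual oxidase that makes hydrogen peroxide at epithelia and in the thyroid. There were 2 libraries per genotype. The total count was 46252203 and 36268530 in WT replicates 1 and 3, and 40984877 and 46212166 in mutant replicates 2 and 4. Each library had between 27538 and 27772 genes with at least 1 count, and the 10 most abundant genes held 9.78% to 10.46% of counts. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 27.7 for the WT pair. Libraries of 1 genotype correlated at 0.97 on log2 CPM across genes, and libraries of different genotypes at 0.927 to 0.933. The first principal component held 64.7% of the variance and separated the genotypes.

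The comparison of mutant with WT asked which transcripts differ in larvae that lack normal duox. The duox transcript itself (ENSDARG00000062632, chromosome 25, 32936356 to 32997271, plus strand, Zv9) was lower in both mutant libraries. It had 279 and 246 counts in the WT libraries and 28 and 57 in the mutant libraries, or 6.39 ± 0.323 CPM against 0.969 ± 0.430 CPM (SD, n = 2 each). The log2 fold change was -2.71 (SE 0.345, adjusted p = 0.00854). In the authors' event lists, the first duox transcript start lay at 32936356 and 32936453 in the WT libraries and at 32948994 and 32988878 in the mutant libraries, where fewer reads covered the gene. The transcript of duoxa, a maturation factor of the oxidase listed in the table as DUOXA2, had 11 and 14 counts in WT and 6 and 2 in the mutant, and its difference did not pass the test (log2 fold change -1.70, adjusted p = 0.404).

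Of 25741 genes tested, 1050 changed, 515 higher and 535 lower in the mutant. Among them, 862 differed by at least 2-fold, 423 higher and 439 lower. Among the 1050 were 297 of the authors' new genes, so 9.54% of new genes tested changed, against 3.33% of Ensembl genes. A further feature was near-absence in 1 genotype, mostly among the authors' new genes. Of changed genes, 84 (27 of them Ensembl genes) had 3 or fewer counts over both WT libraries. A further 124 (45 of them Ensembl genes) had 3 or fewer over both mutant libraries. The count was lower with a mutant library left out, at 568 without mutant replicate 2 and 409 without mutant replicate 4. On simulated data 36 of 172 calls were unchanged genes, a larger share than the threshold of 0.05 implies. Of 100 simulated genes changed by 1 on the log2 scale, all with a mean CPM of at least 1 in the real data, 40 were found. The count was 1767 with DESeq2, 1978 with edgeR's exact test, and 622 and 591 with limma on log2(FPKM + 1) and log2(FPKM + 0.1).

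The largest rises among genes chosen by the rule for named genes included some with no counts in WT. CAPN2 (1 of 4), a calpain protease (ENSDARG00000090014, chromosome 22, 27058678 to 27091551), had 0 counts in WT and 785 and 1522 in the mutant, at least 729-fold higher (adjusted p = 0.00103). MARK3 (1 of 2), a kinase gene (ENSDARG00000077873, chromosome 20, 44242400 to 44290030), had 0 counts in WT and was at least 222-fold higher (adjusted p = 0.000595). The TRIM-type gene btr05 had 1 count in WT and 289 in the mutant, a ratio of 274 (95% interval 48.8 to 10860), and PLXNB2 (4 of 5), a plexin, had 3 and 194, a ratio of 61.3 (20.7 to 299.9). Both of these calls were lost without mutant replicate 4 (adjusted p = 0.0761 and 0.101), as was that of the uridine phosphorylase upp2 (log2 fold change 4.78, adjusted p = 0.0531 without it). The membrane protein gene mal rose from 0.0956 ± 0.0210 to 14.4 ± 2.16 CPM, by 7.17 on the log2 scale. HSD17B7 (2 of 2), of a family with a step in cholesterol synthesis, rose by 5.77, and the hatching enzyme he1a by 5.61, from 0.0759 ± 0.0449 to 3.72 ± 0.650 CPM. The he1a and he1b models overlap on chromosome 22, so their reads cannot be separated. The sodium pump regulator fxyd1 rose from 0.259 ± 0.0531 to 8.30 ± 0.224 CPM, CYLC2 by 3.59, the ferric reductase cybrd1 by 3.46 and ME1 (2 of 2), a malic enzyme, by 3.46, all with an adjusted p of 0.00361 or less.

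Among the 12 largest falls, ubxn1 and INTS5 (2 of 2) had no counts in the mutant. On the contig Zv9_scaffold3489, ubxn1 (ENSDARG00000086797, 132634 to 143489) had 729 and 484 counts in WT and 0 in both mutant libraries, at least 426-fold lower (adjusted p = 0.000426). A second gene of that name, ubxn1 on chromosome 14 (ENSDARG00000090309), named after its values were seen, rose by 0.98 (adjusted p = 0.0315; 0.0649 without WT replicate 3 and 0.135 without mutant replicate 4). INTS5 (2 of 2), an Integrator subunit on the same contig (57850 to 64487), had 0 counts in the mutant and was at least 154-fold lower. The RNA-binding gene bicc2 had 262 and 2 pooled counts, a ratio of 138 (95% interval 37.9 to 1147), and CD40 (6 of 12), of the CD40 receptor family, had 309 and 3, a ratio of 109 (36.8 to 529.6). RSF1 (2 of 3), a chromatin remodelling factor, fell by 5.52 on the log2 scale, from 15.0 ± 0.591 to 0.323 ± 0.0466 CPM, and the MHC class I gene mhc1uba fell by 5.40. The cytochrome P450 gene cyp2p9 fell by 5.08, from 33.3 ± 6.68 to 0.993 ± 0.678 CPM. SSH3 (2 of 2) fell by 4.66, LRRC47 (1 of 2) by 3.90 and the odorant receptor or133-2 by 3.75. The glutathione transferase gstal fell by 3.83 (adjusted p = 0.00911), with unequal WT libraries of 6157 and 1763 counts, and was not called without mutant replicate 2 (adjusted p = 0.0748) or 4 (0.0685). The mitochondrial gene mt-co3 fell to 0.779 ± 0.698 CPM (adjusted p = 0.0133; 0.0686 without mutant replicate 2), but stood at 25.3 ± 18.2 CPM in WT where the median of 11 other mitochondrial genes was 1100 CPM. The span of mt-co3 (9743 to 10500) lies within that of mt-atp6 (9028 to 10510) on the same strand, so their reads cannot be separated. Genes with a number in brackets, such as INTS5 (2 of 2), have copies, as do ubxn1, bicc2, mal and fxyd1. Reads cannot be assigned between copies with certainty.

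Genes of red blood cells were lower in the mutant as a group. Of 24 members tested in the erythrocyte and globin list, 12 fell and none rose (16 fell adjusted over the list alone), with a median log2 fold change of -1.002 (camera adjusted p = 6.34e-13). With an estimated correlation the adjusted p = 0.907. The embryonic globin hbae1 fell from 205 ± 0.880 to 45.6 ± 7.06 CPM (log2 fold change -2.17, SE 0.159, adjusted p = 0.00107), and hbbe1.2 from 81.4 ± 17.1 to 14.8 ± 0.223 CPM (-2.46). The anion exchanger of red cells, slc4a1, fell from 63.9 ± 6.71 to 13.3 ± 1.96 CPM (-2.27, adjusted p = 0.00107), and alas2, the erythroid enzyme that starts heme synthesis, from 27.5 ± 0.261 to 10.7 ± 0.511 CPM (-1.36, adjusted p = 0.00361). The calls of these 4 genes held under every alternative run. The globin genes are close copies of one another, so the value of each single globin is uncertain. Of 37 members of the endothelium and vasculature list, 2 fell, the apelin receptor aplnra (-1.08, adjusted p = 0.0231) and fli1b (-0.97, adjusted p = 0.0359), and 3 fell adjusted over the list alone, without a call for the list (adjusted p = 0.132). The call of aplnra was lost without WT replicate 3, mutant replicate 2 or mutant replicate 4 (adjusted p = 0.0502, 0.0987 and 0.0756), and that of fli1b without WT replicate 1, mutant replicate 2 or mutant replicate 4 (0.1, 0.0738 and 0.146). With limma on log2(FPKM + 1), fli1b was at -0.44 (adjusted p = 0.214).

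**Figure D1:**
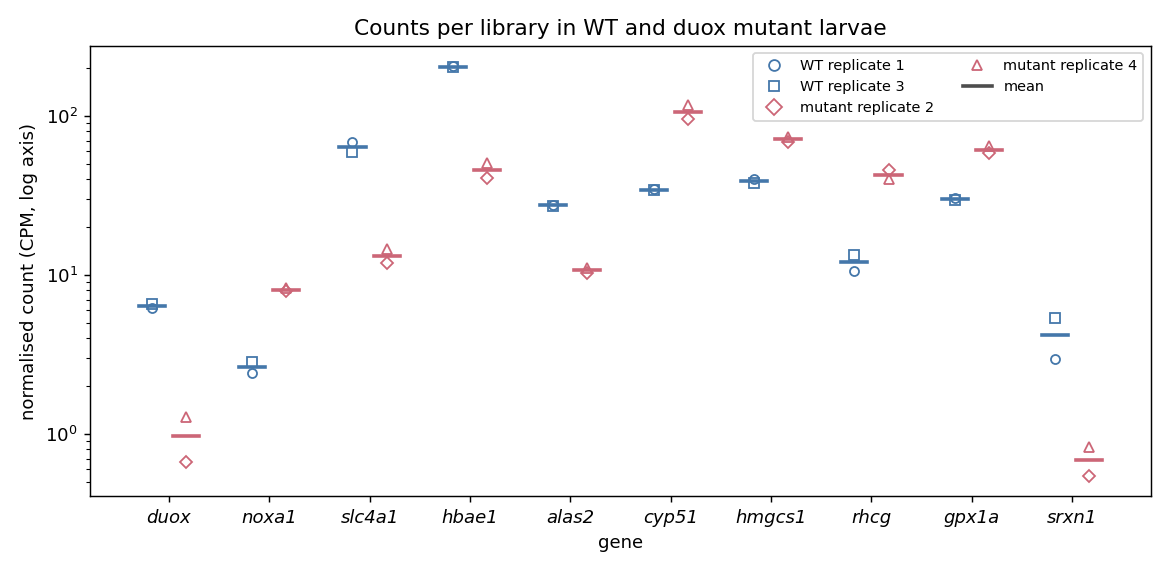
Normalised counts (CPM, log axis) of 10 named genes in each library, with WT replicates in blue, mutant replicates in red and bars for the mean of 2 libraries. In each gene both libraries of one genotype lie above both of the other, as for slc4a1 with means of 63.9 and 13.3 CPM.

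Some genes of cholesterol synthesis rose in the mutant. Of 38 members tested in the bile acid and cholesterol list, 5 rose and none fell (6 rose and 1 fell adjusted over the list alone), 9 had a log2 fold change under 0 and the median was 0.21 (camera adjusted p = 0.00952). With an estimated correlation the adjusted p = 0.954, and the call was also lost without WT replicate 3 (0.091) and without mutant replicate 4 (0.0679). The demethylase cyp51 rose from 34.4 ± 0.263 to 107 ± 14.9 CPM (1.63, SE 0.153, adjusted p = 0.00261), and the squalene epoxidase SQLE (1 of 2) from 5.13 ± 0.0957 to 15.9 ± 1.63 CPM (1.63, adjusted p = 0.00431). Upstream of these, hmgcs1 rose by 0.87 (adjusted p = 0.0167), and downstream sc4mol rose from 21.8 ± 1.96 to 46.9 ± 11.2 CPM (adjusted p = 0.0259). The call of hmgcs1 was lost without WT replicate 3 or mutant replicate 4 (adjusted p = 0.0711 and 0.0733), and that of sc4mol without WT replicate 1 or mutant replicate 4 (0.0531 and 0.0782). The fatty acid list had no changed member of 38 (adjusted p = 0.959), and the glycolysis and gluconeogenesis list had 1 that fell of 39 (3 rose and 3 fell adjusted over the list alone, list adjusted p = 0.959), zgc:73056 (-0.69, adjusted p = 0.0405), whose call was lost with each of the 4 libraries left out in turn (0.0988 to 0.153).

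Genes of drug and steroid metabolism changed in both directions, with 4 of 53 members of the xenobiotic list higher, 5 lower and no call for the list (adjusted p = 0.65). Adjusted over the list alone, 9 rose and 10 fell. The vitamin D hydroxylase cyp24a1 rose from 15.8 ± 0.388 to 62.8 ± 13.8 CPM (1.99, adjusted p = 0.00253), and cyp2aa8 rose by 1.75 while cyp2x9 fell by 1.76. In the gut, liver and pancreas lists, 1 of 37 enterocyte members rose and 3 fell (5 and 5 adjusted over the list alone). An apolipoprotein B gene, APOB (3 of 3), fell by 2.84 on the log2 scale (adjusted p = 0.00283) and AMN fell by 1.31, while si:dkey-7f3.15 fell to 8.83 ± 2.01 CPM and tm4sf4 rose by 0.61. Of 31 genes of exocrine pancreas enzymes, 2 fell (1 rose and 6 fell adjusted over the list alone), the lipase cel.2 (-1.01, adjusted p = 0.0122) and zgc:92511 (-1.42, adjusted p = 0.0385), and of 35 hepatocyte genes agxtb rose by 0.90 and cyp2ad2 fell by 0.67. None of these 3 lists was called (adjusted p = 0.68, 0.54 and 0.65). The calls of AMN and cel.2 were lost without either mutant library (adjusted p = 0.0625 to 0.0698), those of si:dkey-7f3.15 and zgc:92511 without mutant replicate 2 (0.0842 and 0.0825), that of agxtb without WT replicate 1, WT replicate 3 or mutant replicate 4 (0.0541 to 0.0869), and those of tm4sf4 and cyp2ad2 with each of the 4 libraries left out in turn (0.0974 to 0.275).

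In the lists closest to the function of duox, few genes other than duox changed. Of 27 members of the thyroid hormone list, duox alone passed the test, over all genes and adjusted over the list alone. The list was not called (adjusted p = 0.65), with a median log2 fold change of 0.155, a mean of -0.008, 18 members higher and 9 lower. The tests of this list and of the NADPH oxidase list include duox itself, whose fall counts against a rise of other members. They were not repeated without duox. Thyroglobulin, tg, named after its values were seen, stood at 23.5 and 19.9 CPM in the WT libraries and at 33.9 and 25.5 CPM in the mutant libraries (0.45, adjusted p = 0.273). The hormone receptor thraa stood at 12.8 ± 0.751 and 9.65 ± 0.0464 CPM (-0.41, adjusted p = 0.255), and the hormone-responsive klf9 stood at 30.7 ± 1.66 and 38.8 ± 2.49 CPM (0.34, adjusted p = 0.272). Of 26 members of the hypothalamus and pituitary list none changed (adjusted p = 0.662). Among 14 NADPH oxidase genes and partners (adjusted p = 0.65), duox fell and noxa1, an activator of NADPH oxidase 1, rose from 2.63 ± 0.280 to 8.11 ± 0.216 CPM (1.63, SE 0.215, adjusted p = 0.00967; 0.0536 without mutant replicate 4 and 0.0546 with limma on log2(FPKM + 0.1)).

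Antioxidant genes moved both ways. Of 42 members, 2 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.305). The glutathione peroxidase gpx1a rose from 30.1 ± 0.428 to 61.4 ± 4.24 CPM (1.03, adjusted p = 0.00922). The sulfiredoxin srxn1 fell from 4.17 ± 1.68 to 0.686 ± 0.198 CPM (-2.59, adjusted p = 0.019), a call that was lost without mutant replicate 2 (adjusted p = 0.102) or 4 (0.0804) and with limma on log2(FPKM + 1) (-1.07, 0.0708) and log2(FPKM + 0.1) (-2.23, 0.0699). The cystine transporter SLC7A11 (1 of 2) rose by 1.01 on counts (adjusted p = 0.0264), but its change on log2(FPKM + 1) was -0.04, and the call was lost without WT replicate 1, mutant replicate 2 or mutant replicate 4 (0.071, 0.0718 and 0.116). In the heat shock list 1 of 26 rose (adjusted p = 0.622), zgc:174006 (1.23, adjusted p = 0.0269). Its call was lost without WT replicate 1, mutant replicate 2 or mutant replicate 4, with log2 fold changes of 1.215, 1.334 and 1.14. On log2(FPKM + 1) it was at 0.81 with adjusted p = 0.0746. It lies within the span of hsp70 on the other strand, which was not called (0.81, adjusted p = 0.0761). Since the use of strand in counting is not known, reads of zgc:174006 and hsp70 cannot be separated. In the hypoxia list 2 of 30 rose (2 rose and 1 fell adjusted over the list alone, list adjusted p = 0.336), igfbp1b by 1.16 (0.0677 without mutant replicate 4) and ndrg1l by 0.91 (0.104 without WT replicate 1 and 0.1 without mutant replicate 4). No member of the endoplasmic reticulum stress list (30 genes, adjusted p = 0.0605) or the p53 and apoptosis list (26 genes, adjusted p = 0.959) changed.

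Among immune genes, the cytokine il1b rose from 0.652 ± 0.0466 to 3.50 ± 1.59 CPM (2.42, adjusted p = 0.0259; 0.168 without mutant replicate 4), and the transcription factor genes fos and junbl fell by 1.86 and 0.74. With limma on log2(FPKM + 1) and log2(FPKM + 0.1), il1b was at 0.85 and 1.51 and was not called (adjusted p = 0.146 and 0.152). The genes il1b, fos and junbl were the 3 changed genes of 26 in the inflammatory list (3 rose and 3 fell adjusted over the list alone, list adjusted p = 0.219), and the call of junbl was lost with each of the 4 libraries left out in turn (0.0541 to 0.168). In the complement and acute phase list, 1 of 33 rose and 3 fell (3 and 6 adjusted over the list alone, list adjusted p = 0.65), among them the C1 inhibitor gene SERPING1, from 21.2 ± 2.67 to 6.37 ± 0.994 CPM (-1.74, adjusted p = 0.00408). Of 23 macrophage and microglia genes, the cathepsins ctsba (0.88, adjusted p = 0.0144) and ctssb.2 (0.89, adjusted p = 0.0483) rose, without a call for the list (adjusted p = 0.0829). The call of ctsba was lost without WT replicate 1 (0.0698) or mutant replicate 4 (0.0653), and that of ctssb.2 without WT replicate 1, WT replicate 3 or mutant replicate 4 (0.0693, 0.0955 and 0.143). No gene changed among 16 neutrophil markers (adjusted p = 0.622) or 28 interferon and antiviral genes (adjusted p = 0.132).

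A further 4 lists passed camera, each by small shifts. In the cell cycle and DNA replication list, 2 of 36 fell, rrm2 from 52.7 ± 4.99 to 22.3 ± 4.28 CPM (-1.24, adjusted p = 0.0123; 0.05 without mutant replicate 2) and mcm3 from 21.1 ± 0.958 to 2.91 ± 2.67 CPM (-2.85, adjusted p = 0.0403; 0.0562 with DESeq2), with 32 members lower and a median of -0.29 (camera adjusted p = 5.28e-05). With an estimated correlation the adjusted p was 0.954 for this list. In the photoreceptor list, 3 of 59 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.000471; adjusted p = 0.907 with an estimated correlation). The arrestin SAG (1 of 2) fell by 1.37 and ROM1 (1 of 2) by 0.99, while the red opsin opn1lw1 rose by 1.45 and guca1e by 0.85. The calls of SAG (1 of 2) and ROM1 (1 of 2) were lost without either mutant library (adjusted p = 0.06 to 0.12), that of opn1lw1 without mutant replicate 4 (0.074), and that of guca1e without WT replicate 1, mutant replicate 2 or mutant replicate 4 (0.128 to 0.155). With limma on log2(FPKM + 1), SAG (1 of 2) was at -0.64 (adjusted p = 0.28) and guca1e at 0.64 (0.122), without a call. All 65 ribosomal protein genes had a log2 fold change above 0, with a median of 0.18 and none changed (camera adjusted p = 0.0151; adjusted p = 0.954 with an estimated correlation). That direction turned without WT replicate 3 (adjusted p = 0.931) and without mutant replicate 4 (0.609). In the cartilage and bone list, hapln1b fell (-0.84, adjusted p = 0.0482; 0.0532 with RLE scaling and with limma on log2(FPKM + 1), and 0.0721 to 0.199 without WT replicate 3, mutant replicate 2 or mutant replicate 4), alone of 33 and not when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0225; 0.091 without WT replicate 3 and 0.474 without mutant replicate 4). With an estimated correlation the adjusted p of this list was 0.954.

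**Figure D2:**
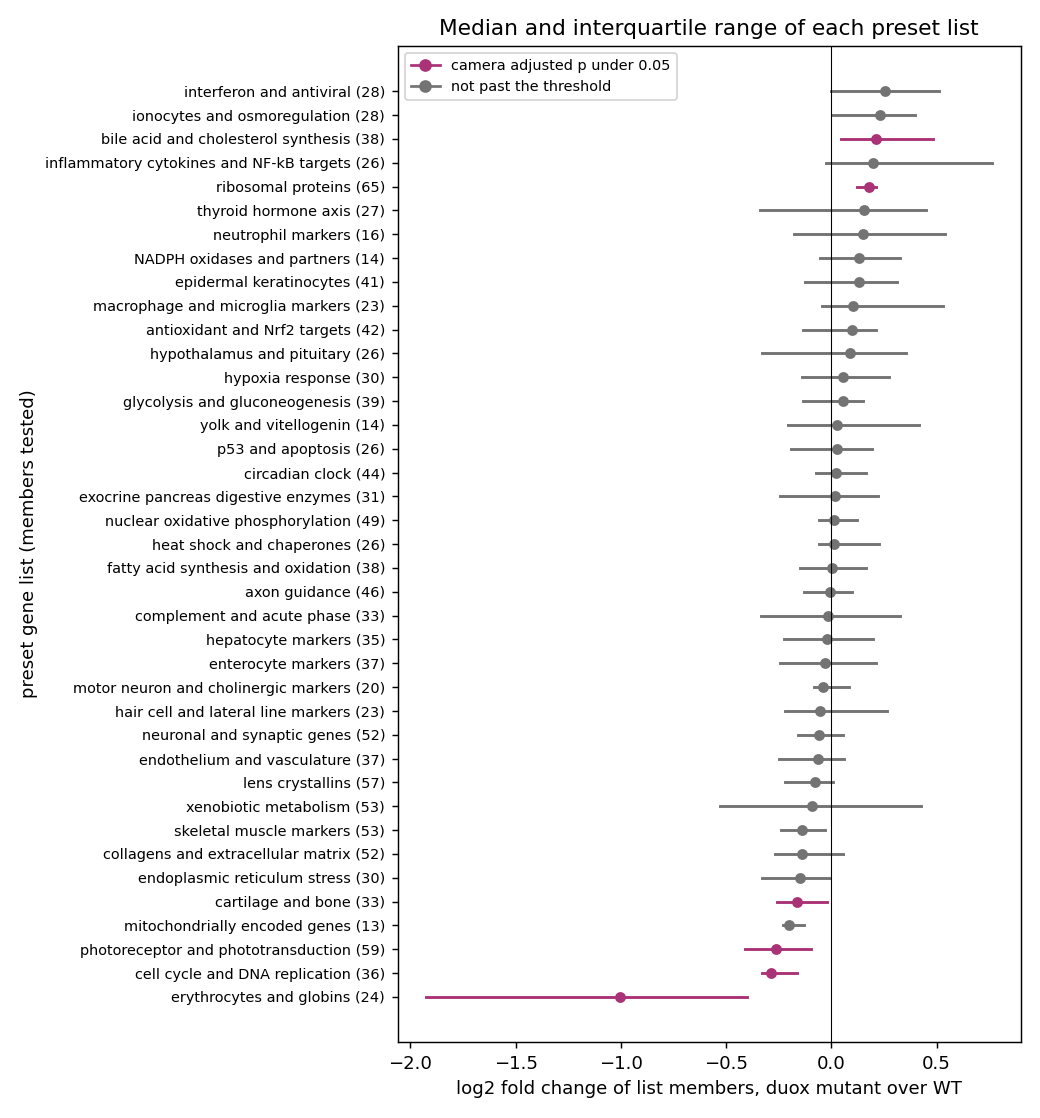
Median (point) and interquartile range (line) of the log2 fold changes, mutant over WT, of the members of each of 39 gene lists, with the number of members tested in brackets. The 6 lists past camera with a preset correlation are in colour, and the erythrocyte and globin list lies farthest from 0 at -1.002.

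The remaining lists were not called. Of 28 ionocyte genes, the ammonia transporter rhcg rose to 42.9 ± 4.08 CPM (1.83, adjusted p = 0.0026) and stc1l fell by 0.88 (list adjusted p = 0.0533), a call lost with each of the 4 libraries left out in turn (0.0693 to 0.119). Of 41 epidermal keratinocyte genes 2 fell (2 rose and 2 fell adjusted over the list alone, list adjusted p = 0.227), zgc:136902 (-3.44) and zgc:113413 (-0.73), the latter call lost with each of the 4 libraries left out in turn (0.0684 to 0.148) and with limma on log2(FPKM + 1) (0.0592). Of 53 skeletal muscle genes, myhc4 fell by 0.93 (0.0659, 0.0615 and 0.0804 without WT replicate 1, mutant replicate 2 and mutant replicate 4, and -0.67 with adjusted p = 0.415 on log2(FPKM + 1), list adjusted p = 0.0673), and of 49 nuclear genes of oxidative phosphorylation, the cytochrome c gene CYCS rose by 1.06 (list adjusted p = 0.54). Of 13 mitochondrially encoded genes mt-co3 alone changed (list adjusted p = 0.148). No member changed in the lists for collagens and extracellular matrix (52 genes, adjusted p = 0.0673), lens crystallins (57, 0.219), neuronal and synaptic genes (52, 0.516), the circadian clock (44, 0.822), motor neurons (20, 0.932), hair cells and the lateral line (23, 0.932), yolk (14, 0.932) and axon guidance (46, 0.959). In every list not mentioned with its own count, the count adjusted over the list alone equalled that over all genes. Median and mean differed in sign, with no call, in the lists for exocrine pancreas, NADPH oxidases, thyroid hormone, glycolysis, motor neurons and axon guidance. The lists for NADPH oxidases and thyroid hormone include duox itself. By fry's mixed test, which takes the members of a list together in either direction, 25 of the 39 lists passed (adjusted p under 0.05). Among them were lists with no changed member, such as lens crystallins. No list passed fry's directional test.

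The authors' deposited table of changed genes lists 375 genes as higher and 360 as lower in the mutant. Of these, 646 were among the 1050 genes found here, where 29.98 would be shared by chance, and all 646 had the same direction. With an adjusted p of 0.01 and a fold of 2, the thresholds the authors' table names, the test used here called 316 genes, of which 310 were on the authors' list. In the authors' deposited table duox has a log2 fold change of -2.72 and an FDR of 2.11E-10. Since both used the same libraries, this compares methods and not samples.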

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

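The fits without genes at 3 or fewer counts in a genotype and on Ensembl genes alone were chosen after the data were seen. No paired analysis was run because the labels do not say whether WT and mutant libraries were collected in pairs. The fall of duox kept its direction and its call under every alternative that could give a value (limma on FPKM could not, since its mean FPKM was under 1), with log2 fold changes from -3.25 without mutant replicate 4 to -2.32 without mutant replicate 2. With a lone library left in a genotype, that library is assumed to vary like those of the other. The number of changed genes, 1050 (515 higher, 535 lower), became 1767 (880, 887) with DESeq2, 1978 (993, 985) with edgeR's exact test, 622 (313, 309) with limma on log2(FPKM + 1) and 591 (291, 300) on log2(FPKM + 0.1). It ranged from 409 (196, 213) without mutant replicate 4 to 1100 without WT replicate 3, with 601 higher there and at most 534 lower without WT replicate 1. A mean CPM of at least 1 left 344 lower, and without genes at 3 or fewer counts in a genotype 692 changed, 331 of them lower, where fewer genes were tested. The cause of the other shifts was not tested. Of 75 changed named genes other than duox, 35 passed the threshold under every alternative and 39 lost it without 1 of the libraries.

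The 6 lists called by camera became 0 with an estimated correlation, 0 with directional fry and 25 with mixed fry, and 6 to 16 when 1 library was left out, most without mutant replicate 2. With an estimated correlation the adjusted p was 0.907 (erythrocytes, photoreceptors) or 0.954 (cell cycle, cholesterol, ribosome, cartilage). With directional fry it was 0.171 (erythrocytes), 0.852 (cell cycle), 0.361 (photoreceptors), 0.448 (cholesterol), 0.872 (ribosome) and 0.721 (cartilage), and with mixed fry 0.14 (cell cycle) and 0.676 (ribosome). Without 1 library the adjusted p ran from 0.00438 to 0.091 for cholesterol, from 4.31e-08 to 0.931 for ribosome, whose direction turned at 0.609 and 0.931, and from 0.00106 to 0.474 for cartilage. The overlap with the authors' list fell from 646 to 310 at the stricter threshold.

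Among the named genes reported here, directions turned for 3. On log2(FPKM + 1) and log2(FPKM + 0.1), SLC7A11 (1 of 2), which rose by 1.01 on counts, was at -0.04 in both, and B2M (2 of 2), at -0.51 on counts and not called (adjusted p = 0.186), was at 0.12 in both. The value of mt-atp6, 2.19 and not called (adjusted p = 0.273), ran from -0.39 without mutant replicate 4 to 3.07 without mutant replicate 2. The cause was not tested. Depth limits genes of few counts, such as duoxa with 33 counts in all.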

Other observations

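The test of haplotypes at loci not linked to duox and that of a segment linked to duox were fixed before their results were seen, except that the former was later limited to genes past the test; the tests of gene copies, of single chromosomes and windows, and of the erythroid genes were chosen after.

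Some genes outside the rule for named genes were chosen after their values were seen. The transcription factor genes fosb and egr1 fell by 1.57 (adjusted p = 0.0218) and 0.94 (adjusted p = 0.0495), btg2 from 169 ± 12.6 to 60.4 ± 16.7 CPM (-1.49, adjusted p = 0.0112), and the phosphatase gene dusp1 from 82.8 ± 2.37 to 44.6 ± 1.72 CPM (-0.89, adjusted p = 0.0144). The calls of fosb and egr1 were lost without mutant replicate 4 (adjusted p = 0.0999 and 0.138), that of egr1 also without WT replicate 1 (0.0919) and with RLE scaling (0.0553) and limma on log2(FPKM + 1) (0.0615), and that of dusp1 without mutant replicate 2 (0.0533) or 4 (0.0817). The retinal homeobox gene rx2 rose from 6.46 ± 1.14 to 36.3 ± 1.66 CPM (2.49, adjusted p = 0.000992), and the fatty acid elongase elovl4a from 5.21 ± 0.596 to 19.1 ± 0.671 CPM (1.87, adjusted p = 0.00222). On chromosome 4 the ms4a family genes ms4a17a.2, ms4a17a.4 and ms4a17a.5 rose by 2.90, 2.03 and 2.85 (adjusted p = 0.0298, 0.0291 and 0.005), and the calls of ms4a17a.2 and ms4a17a.4 were lost without mutant replicate 4 (0.18 and 0.131), that of ms4a17a.4 also with limma on log2(FPKM + 1) (0.90, adjusted p = 0.107).

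Changed genes were unevenly placed in the genome. Chromosome 16 held 61 changed genes of 949 tested (6.43%, against 3.02% on the other chromosomes, Fisher's exact adjusted p = 4.56e-06 over 25 chromosomes, odds ratio 2.21, 95% interval 1.65 to 2.91). Chromosome 4 also held a larger share (4.94%), and chromosomes 13 and 21 smaller shares (1.6% and 1.52%), each with an adjusted p of 0.0362. Of 284 windows of 5 Mb, 9 held more changed genes than the rest of the genome (Fisher's exact, adjusted p under 0.05), with 89 changed of 681 tested. The smallest adjusted p, 0.000685, was that of chromosome 22 from 5 to 10 Mb (14 of 98) and of chromosome 4 from 60 to 65 Mb (11 of 64). The window on chromosome 3 from 55 to 60 Mb, with 9 of 83 and the largest adjusted p of the 9 (0.0393), contains hbae1 and hbbe1.2, whose spans overlap. The window on chromosome 16 from 45 to 50 Mb held 11 of 92 and contains SQLE (1 of 2) and fxyd1. Fisher's test treats neighbouring genes as independent, so neighbouring copies of 1 family that change or share reads together can raise the count of a window. The windows were not tested with such copies counted once.

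Near-absence in 1 genotype or a change of at least 8-fold was found for 345 changed genes, of which 156 carry Ensembl identifiers. Of the 1050 changed genes 715 have a position, and the rest could not be placed near duox or elsewhere. For placed changed genes of any size, a segment linked to duox is argued against as a source, since 3 of 229 genes within 10 Mb of duox changed, against 711 of 21354 elsewhere (odds ratio 0.385, exact 95% interval 0.0787 to 1.15). For the strongly changed genes alone, 0 of 229 against 136 of 21354 (interval of the odds ratio 0 to 2.57) is too few to exclude an excess near duox. The 136 of these 345 genes that have a position lie elsewhere. A candidate explanation is that haplotypes at loci not linked to duox differ between the WT and mutant clutches: on other chromosomes the 117 strongly changed genes with a position formed 8 neighbouring pairs, where 1000 shuffles within chromosomes gave 0.807 on average and at most 6 (one-sided permutation p = 0.001, the smallest they can give). Of the 8 pairs, all in the same direction, 2 overlapped, 4 were of 1 gene family and 4 were neither. The permutation p counts the overlapping and family pairs as well, and no shuffles were run for the other 4 alone. Those 4 include CU914813.1 paired with CABZ01067657.1 and again with CYLC2 on chromosome 15, so they are not all separate loci. Neighbours that respond together would give such pairs too. The pairs therefore do not decide whether haplotypes differ. That reads pass between copies of a gene is another candidate explanation, for those with copies: in 24 of 28 gene families (85.7%, exact 95% interval 67.3% to 96.0%) the median of the other copies went the opposite way, by a median of 0.19 on the log2 scale over the families, and a response of the copies themselves would look the same. This count by family replaced, after the values were seen, a count by copy that listed copies more than once and in the NLRX1 family was fixed by strongly changed genes in both directions. By copy, 58.2% of 134 were opposite (exact 95% interval 49.4% to 66.7%), which did not exclude an even split. An effect of the duox genotype itself stays among the open explanations, untested.

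Erythroid genes were lower in the mutant. A first test, the median log2 fold change of the 15 members that are not globins (-0.40, SE 0.217), left it undecided whether reads shared between globin copies were the cause, and a sum over the globins replaced it after their values were seen. Reads passing from 1 to another of the 9 globin genes are argued against as the cause, since the CPM summed over them went from 1390 ± 287 to 515 ± 107 (log2 ratio -1.43), and 4 of the 15 members that are not globins also fell. The sum cannot tell whether reads were dropped or passed to genes outside the 9, since the treatment of reads that match several places is not known. Fewer red blood cells as the whole cause would lower the globins by 1 common factor, if the proportions of globins in the cells stayed the same. Their log2 fold changes instead ran from -3.70 to -1.07 with a Cochran's Q of 66.8, where a common factor gives 8 on average. Reads misassigned between copies differently in each genotype could also give such a spread. A difference in red cell number combined with a shift in which globins are made, or with a haplotype at the globin locus, remains open, as does an effect of the duox genotype.

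The mitochondrial gene mt-atp6 had 4949 counts in mutant replicate 2 and 58198 in mutant replicate 4, while the 11 mitochondrial genes other than mt-atp6 and mt-co3 had log2 fold changes from -0.31 to 0.17. Since the span of mt-co3 lies within that of mt-atp6 on the same strand, the reads of these genes cannot be separated.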
